A study of Nothobranchius furzeri with 185 samples.

How the data were processed

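The deposited table of read counts per gene was used for every test, and the deposited RPKM table (reads scaled by gene length and depth) only to derive gene lengths. Per the file headers both hold 185 libraries, each matched to its labels by the fish code, tissue or age in its column name. Total RNA was extracted with QIAzol and about 2.5 µg (liver, skin and brain) or 1 µg (fins) went into TruSeq RNA libraries, per the labels. Per the submitters' processing notes, reads were called with CASAVA 1.8.0 or 1.8.2 and bcl2fastq 1.8.4, mapped with TopHat2 2.0.6 and counted per gene with featureCounts 1.4.3-p1. The genome build and the annotation are not given in the sources used here. The values were checked and hold whole numbers in the first table, and the ratio of both tables gives 1 length per gene within 1 percent in 99.989 percent of values for 18986 genes.

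The gene table has 23564 loci, of which 22036 carry a symbol. Since 9479 loci share their symbol with another locus, lists and tests run on loci, not on symbols. Total counts per library lay between 14.97 and 54.95 M (mega), with a median of 30.51 M. No library is a copy of another of its group, as the closest pair of a group still differs by a chi-square of 11.114 per degree of freedom. Pairs from different groups were not compared in this way.

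Groups, comparisons, tests, gene lists, the rule for naming genes and 127 alternatives were fixed before the data were examined. Each tissue of each arm was fitted in edgeR 4.0.16 (R 4.3.3) with TMM factors, filterByExpr, robust quasi-likelihood dispersions and 1 mean per group, so that all groups of an arm share 1 estimate of spread. Fin ages were compared with fish as replicate block, lifespan groups with the batch named in the titles as covariate, and the change between clips as an age by group term. P values were adjusted by Benjamini-Hochberg over all genes tested, with calls at adjusted p under 0.05. DESeq2 1.42.0 was the second tool, and limma 3.58.1 gave the set tests.

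Sets were 37 gene lists written from general knowledge of metabolism, proteostasis, cell division, matrix, immunity, stress and tissue markers, of which those with at least 5 measured loci were tested. Camera ran on log2 CPM (prior count 2) with an inter-gene correlation of 0.01, and again with a correlation estimated per list, which 2 of 218 results passed. Member counts are given over all genes tested and adjusted over the list alone. In no list past the test did the median or the mean have the opposite sign to the test. RLE size factors in place of TMM moved the median log2 fold change of all genes by at most 0.055.

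Named genes were the 6 largest increases and 6 largest decreases among called genes with a mean log2 CPM of at least 2 that kept their sign with each library left out, up to 4 called members of each list past the set test, the 3 smallest p where nothing was called, and up to 4 complex I subunits under rotenone and between lifespan groups. The text gives part of the 720 names that result.

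Correlations across fish used 1e+05 permutations, and the smallest p these can give is 1e-05. The clock score projects treated libraries on the main axis along which 28 clock genes vary within age groups of untreated livers and skins (38.8 percent of that variance), signed so that nr1d1 is positive. To remove a trend, the deviation of each library from the gene means was smoothed (lowess, span 0.3) on gene length or on the difference between the MC10 brain and the other vehicle brains, and the curve entered the fit as an offset. For brains, the skin difference between 39 and 12 weeks took that place. These offsets, 4 fits without libraries that stand apart and the marker lists of testis and pituitary were chosen after the data were seen.

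The pipeline was tested on simulated data with 50 genes changed per fold. In 39 against 5 weeks 4 percent of 1.5-fold, 18 percent of 2-fold and 76 percent of 4-fold changes were recovered in the liver, and 6, 34 and 84 percent in skin. Rotenone contrasts recovered 70 percent of 2-fold changes in the brain, 30 in the liver and 28 in skin. In the fins 98 percent of 2-fold changes between ages, 90 percent between lifespan groups at 10 weeks and 82 percent for the change between clips were recovered, so that small changes in the tissue arms stay mostly undetected. No sign was wrong, at most 9 unchanged genes were called, and a shifted list was found with no other list beside it. The simulated genes varied independently and no simulated library stood apart. These counts therefore do not show how often genes or lists pass falsely where genes move together. Figures were drawn with matplotlib 3.10.9, and scores computed with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 under Python 3.11.15.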

Results

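Killifish were studied in 3 arms. Liver and skin came from untreated fish of 5, 12, 20, 27 and 39 weeks, brain, liver and skin from fish kept 4 weeks in vehicle (DMSO) or rotenone, and fin clips from 45 fish sampled at 10 and again at 20 weeks and then followed until death. Rotenone blocks complex I of the respiratory chain, and the labels give its dose as 15 pM. All 185 libraries were used, with 5 fish per group in the tissue arms and 15 fish per lifespan group. A gene is called when edgeR gave it an adjusted p under 0.05. Values are log2 fold changes ± standard error, positive when higher in the older or treated fish. A locus identifier follows symbols shared by several loci, whose reads can be exchanged, so that these values are less certain.

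Some libraries stand apart in marker genes, mostly those of another tissue. For yolk and chorion genes, which need not come from another tissue, the 5-week liver of fish JM103 reads 5.761 (mean log2 CPM) and the next fish -0.346. The 12-week skin of JM109 reads 6.313 for hepatocyte genes against at most 2.772. Testis germ-cell genes (ddx4, dazl, sycp1) reach 5.549 in the vehicle skin of MC7 and 6.672 in the rotenone skin of MR30, with no other fish of these groups above -0.299. Muscle genes mark the vehicle livers of MC7 (1.633) and MC8 (1.338). The brain of MC10, labelled vehicle, reads 953 genes at least 8-fold below the mean of the other 4 brains of its group. These MC10-low genes were picked after the data were seen, and they recur below because they read low in 39-week skins and under rotenone too.

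In the liver, genes of DNA replication, fatty acid oxidation and the respiratory chain were lower at 39 than at 5 weeks, and complement C1q and ribosomal genes higher. Of 17618 genes 2111 were called, 919 higher and 1192 lower. The largest rises were 5.80 ± 1.31 for aqp9b Nfu_g_1_008170, 5.08 ± 0.87 for fgf19, 5.05 ± 0.86 for fgf1a Nfu_g_1_005405, 5.00 ± 1.21 for GPR116 (5 of 6) and 4.57 ± 1.09 for arg2, which encode a glycerol channel, 2 growth factors, an adhesion receptor and an arginase. The deepest falls were -14.80 ± 3.06 for vtg2 Nfu_g_1_002309, -12.72 ± 2.36 for wfdc2 Nfu_g_1_014807, -11.87 ± 2.63 for vtg2 Nfu_g_1_002572, -8.56 ± 1.44 for INHBE and -7.26 ± 2.17 for gatm, of which the vtg2 loci encode yolk precursors. The adjusted p of these genes ran from 0.000497 to 0.0318. Of cell cycle and replication genes 45 of 57 were called lower, 52 adjusted over the list alone (adjusted p = 5.75e-38), with the primase and helicase components -3.28 ± 0.34 for prim1, -3.49 ± 0.39 for cdc45 and -4.01 ± 0.46 for mcm5. Of fatty acid oxidation genes 12 of 30 were called lower, 17 and 1 adjusted over the list alone (adjusted p = 2.76e-07), with the acyl-chain enzymes acads at -1.26 ± 0.24 and slc25a20 at -1.34 ± 0.27. Of mitochondrially encoded subunits 8 of 13 were called lower, 10 adjusted over the list alone (adjusted p = 4.32e-07), led by MT-ATP8 (-1.44 ± 0.24). Of nuclear complex I subunits 4 of 30 were called lower, 5 adjusted over the list alone (adjusted p = 0.000773), with -0.79 ± 0.21 for ndufv3 and -0.79 ± 0.23 for ndufa10. Of fatty acid synthesis genes 6 of 32 were called lower and 2 higher, 7 and 2 adjusted over the list alone (adjusted p = 0.000773), with -2.12 ± 0.40 for dgat2 and -4.37 ± 0.89 for elovl6. Of macrophage genes 4 of 28 were called higher, 5 adjusted over the list alone (adjusted p = 0.00122), with 2.59 ± 0.50 for c1qb and 2.47 ± 0.64 for c1qc. Of cytosolic ribosomal proteins 4 of 74 were called higher, 51 adjusted over the list alone (adjusted p = 2.63e-15), with rplp2 at 1.00 ± 0.29. These 7 lists had adjusted p from 0.163 to 0.705 with an estimated correlation. Lower too were mitochondrial ribosome, complexes II to V, proteasome and cholesterol synthesis (adjusted p from 6.63e-08 to 0.0064, and adjusted p = 0.705 with an estimated correlation), with mrps5 at -1.13 ± 0.27. Higher were muscle, B cells and immediate early genes (adjusted p from 0.0017 to 0.00472, and adjusted p = 0.705 with an estimated correlation), with tnnt3a at 4.05 ± 1.28, and muscle genes read highest in the 39-week liver of JM15. Without JM103 the vtg2 falls shrank to -3.0 and -1.57 and were not called. Without JM103 and JM100, aqp9b, GPR116 (5 of 6), arg2 and gatm lost their calls as well, and 1118 genes were called.

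Between 5 and 12 weeks liver replication, proteasome and chaperone genes were lower and hepatocyte and ribosomal genes higher. Of 17618 genes 2383 were called, 971 higher and 1412 lower. Rises were led by 5.77 ± 1.14 for SLC6A16 (1 of 2), 5.19 ± 1.71 for aldh18a1 Nfu_g_1_023226, 5.13 ± 1.39 for MAST1 (1 of 2) and 5.13 ± 1.59 for chrm3a, a transporter, a proline-making enzyme, a kinase and a receptor. Falls were led by -14.81 ± 3.09 for vtg2 Nfu_g_1_002309, -12.78 ± 2.72 for vtg2 Nfu_g_1_002572, -12.54 ± 2.37 for wfdc2 Nfu_g_1_014807, -7.01 ± 1.96 for b3gat1 Nfu_g_1_000167 and -6.60 ± 2.21 for gck, with adjusted p from 0.00159 to 0.0494 over these genes. Of cell cycle and replication genes 51 of 57 were called lower, 54 and 1 adjusted over the list alone (adjusted p = 9.74e-40), with -2.86 ± 0.33 for prim1 and -3.31 ± 0.39 for mcm7. Of proteasome subunits 19 of 44 were called lower and 1 higher, 28 and 1 adjusted over the list alone (adjusted p = 1.69e-09), with -1.76 ± 0.44 for psmc4 and -1.30 ± 0.28 for psma5. Of chaperones 10 of 34 were called lower, 15 adjusted over the list alone (adjusted p = 0.00375), led by hsp90aa1.2 at -5.02 ± 1.27 and hspa9 at -1.97 ± 0.54. Of hepatocyte genes 4 of 41 were called higher and 1 lower, 5 and 1 adjusted over the list alone (adjusted p = 0.0068), with the tyrosine enzyme fah at 1.8 ± 0.46. Of cytosolic ribosomal proteins 25 of 74 were called higher, 66 adjusted over the list alone (adjusted p = 3.22e-18), with 1.12 ± 0.30 for rps28 and 1.14 ± 0.33 for rpl11. These 5 lists had adjusted p from 0.137 to 0.973 with an estimated correlation. Lower too were mitochondrial ribosome, fatty acid synthesis and collagens and matrix (adjusted p from 2.6e-06 to 0.0142, and adjusted p from 0.825 to 0.973 with an estimated correlation), with mrpl37 at -1.20 ± 0.26. Higher were complement and p53 targets (adjusted p from 0.00141 to 0.0281, and adjusted p from 0.825 to 0.973 with an estimated correlation), with fgg at 1.97 ± 0.50 and mdm2 at 1.07 ± 0.26. Without JM103 the vtg2 values were -3.04 and -2.53 and b3gat1 read -0.79, and these and aldh18a1, chrm3a and gck lost their calls. The count was 1498 without JM101, 1497 without JM98, 1214 without JM104, 1427 without JM106 and 1036 without JM103 and JM100.

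From 12 to 39 weeks no single liver gene passed in edgeR, although energy-metabolism lists moved. edgeR called 0 of 17618 genes, 3026 had an unadjusted p under 0.05, and DESeq2 called 508. The smallest p values belonged to the neuropeptide receptor prlhr2a (-3.31 ± 0.60), the synaptotagmin syt5a (2.66 ± 0.48) and the lipid phosphatase mtmr7b (1.30 ± 0.24), each at adjusted p = 0.0564. Without JM18 118 genes were called, without JM115 39, and without JM1 or JM13 1 each. All 13 mitochondrially encoded subunits were lower when adjusted over the list alone, with a median of -0.58. Lower as lists, with 0 members called among all genes, were mitochondrially encoded subunits, complex I, hepatocyte genes, fatty acid oxidation, complexes II to V, complement, erythrocytes, autophagy, p53 targets and cholesterol synthesis (adjusted p from 1.87e-09 to 0.0356, and adjusted p from 0.58 to 0.774 with an estimated correlation). Higher, again with 0 members called, were macrophages, proteasome, B cells, T cells and immediate early genes (adjusted p from 0.000279 to 0.0233, and adjusted p from 0.692 to 0.76 with an estimated correlation). Across all 5 ages 2277 liver genes were called for any difference, of 5853 with an unadjusted p under 0.05. That count was 1107 without JM98, 1349 without JM101, 1350 without JM103, 1479 without JM97, 1503 without JM104 and 3718 without JM83, and DESeq2 gave 4816. The same test on skin called 12580 of 18925 genes, and the bar chart draws the calls of each comparison.

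**Figure D1:**
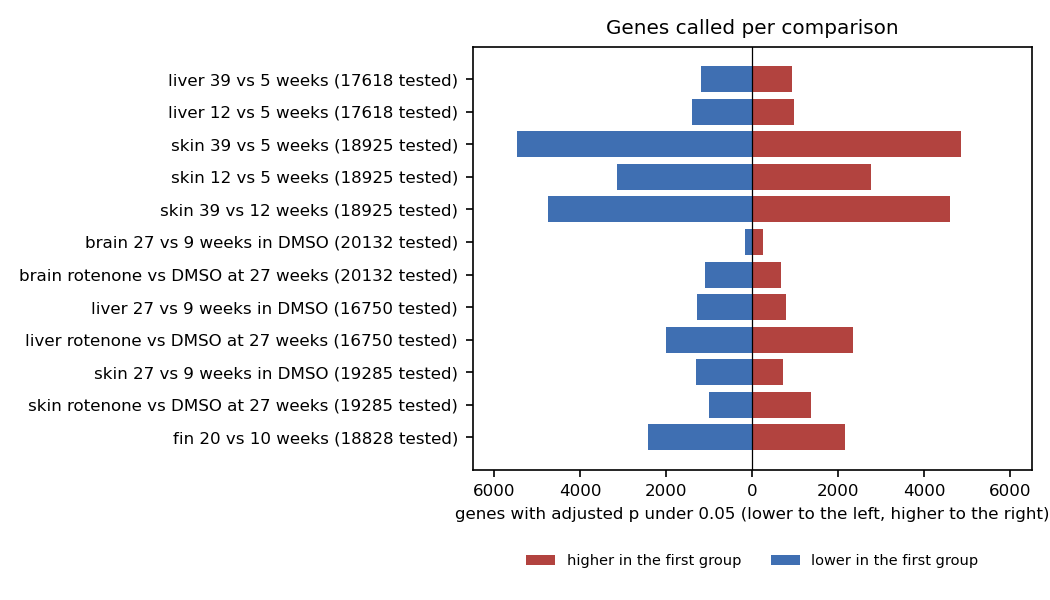
Genes called higher and lower in each of 12 comparisons by edgeR. Bars to the right of the line count genes higher in the older or treated group.

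In skin, proliferation, matrix and mitochondrial genes were lower at 12 than at 5 weeks, and pigment-cell and clock genes higher. Of 18925 genes 5913 were called, 2763 higher and 3150 lower. Leading the falls were -7.54 ± 1.65 for ctsl.1, -7.39 ± 0.95 for col2a1a Nfu_g_1_001498, -6.77 ± 1.81 for fabp6 Nfu_g_1_020514, -5.34 ± 1.66 for lgals2b Nfu_g_1_019860 and -4.02 ± 0.68 for psat1, a protease, a cartilage collagen, a lipid carrier, a galectin and a serine-making enzyme. Leading the rises were 4.14 ± 1.05 for tceb3 Nfu_g_1_021005 and 3.65 ± 0.44 for lhx6 Nfu_g_1_017201, and adjusted p ran from 8.64e-06 to 0.0181. The complement gene c5 (4.00 ± 0.97), agxtb (3.71 ± 0.99), lrp2a (3.61 ± 0.97) and DIABLO (4.06 ± 1.34) owe their rise to the skin of JM109, and without it read 0.50, 0.52, 0.47 and 0.018, none called. Of cell cycle and replication genes 50 of 57 were called lower and 1 higher, 51 and 1 adjusted over the list alone (adjusted p = 7.18e-23), with -3.02 ± 0.34 for pola1 and -2.51 ± 0.27 for dut. Of collagens and matrix genes 45 of 83 were called lower and 5 higher, 53 and 5 adjusted over the list alone (adjusted p = 8.78e-12), with the collagen-modifying enzymes -1.55 ± 0.16 for p4ha1b and -1.94 ± 0.23 for plod1a. Of mitochondrial ribosomal proteins 44 of 62 were called lower and 3 higher, 49 and 3 adjusted over the list alone (adjusted p = 3.06e-12), with -1.71 ± 0.23 for mrpl13 and -1.18 ± 0.18 for mrps10. Of chaperones 19 of 34 were called lower and 2 higher, 22 and 2 adjusted over the list alone (adjusted p = 6.11e-05), with -2.08 ± 0.35 for calrl and -2.49 ± 0.52 for hspd1. Of pigment-cell genes 13 of 26 were called higher, 17 and 1 adjusted over the list alone (adjusted p = 5.94e-06), with the melanocyte channels 2.49 ± 0.44 for trpm1a and 1.74 ± 0.27 for trpm1b. Of clock genes 13 of 28 were called higher, 13 and 1 adjusted over the list alone (adjusted p = 0.00089), with 2.25 ± 0.42 for dbpb and 1.24 ± 0.27 for bhlhe41. These 6 lists had adjusted p from 0.483 to 0.624 with an estimated correlation. Lower too were proteasome, complexes II to V, mitochondrially encoded subunits, fatty acid oxidation, complex I and astroglia (adjusted p from 9.44e-08 to 0.0357, and adjusted p from 0.483 to 0.66 with an estimated correlation), with psmc4 at -1.71 ± 0.37 and MT-ND2 at -0.86 ± 0.15. Higher were cytosolic ribosome, keratinocytes, interferon response, pancreatic enzymes, T cells, complement and hepatocyte genes (adjusted p from 7.23e-07 to 0.0417, and adjusted p from 0.612 to 0.66 with an estimated correlation), with cldn1 at 1.30 ± 0.24 and ifih1 at 0.91 ± 0.28. The hepatocyte list owes its rise to JM109 as well, since the other 12-week skins score 2.523 to 2.772 and 5-week skins 2.809 on average. Removing the MC10-low trend ended the complex I result (adjusted p = 0.874) and gave 6061 calls, with 5216 of the 5913 kept.

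At 39 weeks skin had less collagen and replication transcript than at 5 weeks and more ribosomal, respiratory-chain and immune transcript. Of 18925 genes 10316 were called, 4854 higher and 5462 lower. First among the falls were -6.88 ± 0.58 for CGREF1, -6.82 ± 0.93 for col2a1a Nfu_g_1_001498, -6.75 ± 0.59 for col5a3b and -6.42 ± 0.60 for COL22A1 Nfu_g_1_002140, mostly collagens of cartilage and tendon junctions. First among the rises were 6.53 ± 1.16 for tceb3 Nfu_g_1_021005, 5.53 ± 0.82 for crybb1, 4.85 ± 0.68 for bhmt Nfu_g_1_009142, 4.51 ± 0.54 for mgp and 4.39 ± 0.62 for steap4, where mgp restrains mineral deposition. Adjusted p ran from 9.32e-09 to 5.62e-05. Of collagens and matrix genes 77 of 83 were called lower and 1 higher, 77 and 2 adjusted over the list alone (adjusted p = 1.12e-24), with -2.64 ± 0.17 for p4ha1b and -3.27 ± 0.26 for col5a1. Of cytosolic ribosomal proteins 72 of 74 were called higher, 72 adjusted over the list alone (adjusted p = 1.36e-34), with 2.13 ± 0.17 for rplp2 and 2.07 ± 0.18 for rps26. Of cell cycle and replication genes 43 of 57 were called lower and 1 higher, 45 and 1 adjusted over the list alone (adjusted p = 3.16e-05), with -3.58 ± 0.35 for pola1 and -3.70 ± 0.52 for ESPL1. Of complex I subunits 23 of 30 were called higher, 23 adjusted over the list alone (adjusted p = 6.66e-08), with 1.59 ± 0.19 for ndufa2 and 1.56 ± 0.19 for ndufs5. Of macrophage genes 16 of 28 were called higher and 3 lower, 16 and 3 adjusted over the list alone (adjusted p = 0.00737), with c1qb at 2.39 ± 0.29. Of T-cell genes 10 of 13 were called higher and 1 lower, 10 and 1 adjusted over the list alone (adjusted p = 0.00128), with gzma at 2.61 ± 0.42. These 6 lists had adjusted p from 0.258 to 0.796 with an estimated correlation. Higher too were mitochondrially encoded subunits, complexes II to V, immediate early genes, proteasome, mitochondrial ribosome, antioxidant genes, pancreatic enzymes and interferon response (adjusted p from 0.000984 to 0.0202, and adjusted p from 0.63 to 0.81 with an estimated correlation), with MT-CO2 at 1.07 ± 0.14 and psmb6 at 1.59 ± 0.18. With the MC10-low trend removed, 8544 genes were called, with 6937 of the 10316 kept, and complex I (adjusted p = 0.117), mitochondrially encoded subunits (0.138), complexes II to V (0.682), mitochondrial ribosome (0.132), antioxidant genes (0.569) and proteasome (1.0) no longer passed. Mitochondrial ribosomal and transfer RNA made up 0.225 percent of counts at 39 and 0.038 at 5 weeks, and 21212.8 against 21781 genes were detected on average.

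Between 12 and 39 weeks ribosomal, respiratory-chain and proteasome genes of skin rose, and collagens, pigment-cell and clock genes fell. Of 18925 genes 9340 were called, 4592 higher and 4748 lower. Rises were led by the stress and repair genes 5.07 ± 1.54 for hsp70.1, 5.06 ± 1.56 for ctsl.1, 3.49 ± 0.76 for mmp13a and 3.27 ± 0.75 for ADM (2 of 2). Falls were led by -5.29 ± 1.67 for APOB (1 of 3) Nfu_g_1_018881, -5.28 ± 1.94 for neb Nfu_g_1_005737, -4.81 ± 0.46 for COL7A1, -4.80 ± 1.18 for apobl and -4.75 ± 0.59 for COL12A1 Nfu_g_1_000084, with adjusted p from 9.08e-08 to 0.0277. Without JM109, APOB (1 of 3) read -0.63, apobl -0.32 and neb -4.78, and without JM24 ctsl.1 read 1.91, none of them called. Of cytosolic ribosomal proteins 72 of 74 were called higher, 72 adjusted over the list alone (adjusted p = 6.02e-30), with 1.65 ± 0.17 for rps26 and 1.82 ± 0.20 for rps15. Of complex I subunits 29 of 30 were called higher, 29 adjusted over the list alone (adjusted p = 8.27e-14), with 1.57 ± 0.17 for ndufa13 and 1.64 ± 0.19 for ndufa6. Of proteasome subunits 40 of 44 were called higher, 42 adjusted over the list alone (adjusted p = 8.42e-12), with 2.0 ± 0.24 for psmb2 and 1.92 ± 0.25 for psmb5. Of collagens and matrix genes 63 of 83 were called lower and 1 higher, 66 and 1 adjusted over the list alone (adjusted p = 1.88e-15), with fn1 at -3.22 ± 0.32. Of pigment-cell genes 15 of 26 were called lower and 2 higher, 15 and 2 adjusted over the list alone (adjusted p = 0.00841), with the receptors -2.26 ± 0.31 for mc1r and -1.95 ± 0.28 for kita. Of clock genes 16 of 28 were called lower and 2 higher, 16 and 2 adjusted over the list alone (adjusted p = 0.00841), with -2.08 ± 0.28 for bhlhe41 and -3.60 ± 0.53 for tefb. These 6 lists had adjusted p from 0.409 to 0.797 with an estimated correlation. Higher too were mitochondrial ribosome, complexes II to V, mitochondrially encoded subunits, cell cycle, chaperones, immediate early genes, antioxidant genes, T cells and macrophages (adjusted p from 1.23e-15 to 0.0249, and adjusted p from 0.409 to 0.814 with an estimated correlation), with mrps10 at 1.41 ± 0.18 and hspb1 at 2.42 ± 0.42. Of the MC10-low genes 592 of 666 measured here were called lower, with a median of -2.65 against 0.10 for other genes. Across genes, not independent replicates, the step had r = 0.71 with the MC10 difference. With that trend removed 4259 genes were called, with 3179 of the 9340 kept, and complexes II to V (adjusted p = 0.11), cell cycle (0.746), antioxidant genes (0.921), chaperones (0.796), clock (0.518) and macrophages (0.0928) no longer passed. Scores of these genes are drawn per library.

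**Figure D2:**
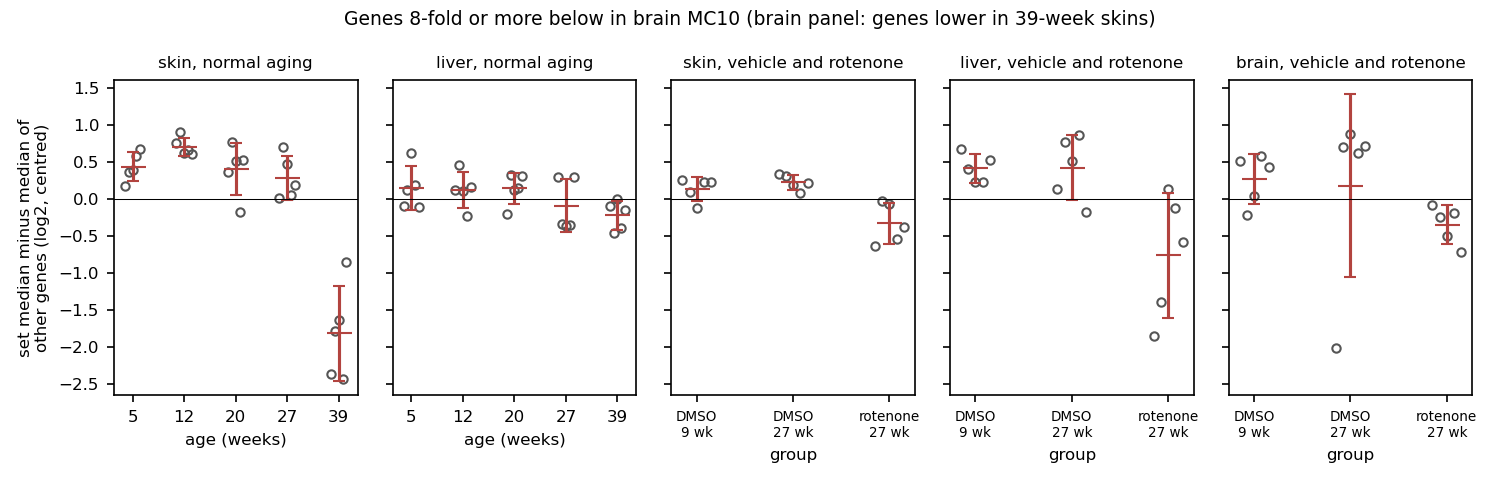
Score of the MC10-low genes in each library by tissue, age and treatment, with group mean ± SD in red. The brain panel uses genes lower in 39-week skins, so that the MC10 brain does not define its own score.

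In vehicle-treated fish, mitotic genes of the brain were lower at 27 than at 9 weeks and immune genes higher. Of 20132 genes 420 were called, 241 higher and 179 lower, and 3418 had an unadjusted p under 0.05. Leading the falls were -2.19 ± 0.40 for anln, -2.02 ± 0.40 for aspm, -1.93 ± 0.27 for dlb and -1.61 ± 0.34 for cenpf, which act in cell division and in Notch signalling. Leading the rises were 6.59 ± 1.58 for OSBPL3 (1 of 2) Nfu_g_1_012123, 4.26 ± 1.00 for mmp13a, 3.09 ± 0.74 for ncf1 and 2.50 ± 0.52 for CD22 (2 of 39), among them a matrix protease, an oxidase subunit of phagocytes and a B-cell receptor. Adjusted p ran from 0.00666 to 0.0442. Of cell cycle and replication genes 3 of 58 were called lower, 27 and 1 adjusted over the list alone (adjusted p = 6.21e-17), with -1.02 ± 0.18 for smc4 and -1.45 ± 0.33 for tk1. Of macrophage and microglial genes 5 of 29 were called higher, 16 adjusted over the list alone (adjusted p = 1.14e-07), with 1.66 ± 0.24 for c1qc and 0.92 ± 0.17 for mrc1b. Of complement genes 3 of 32 were called higher, 7 adjusted over the list alone (adjusted p = 1.52e-07), with 1.43 ± 0.26 for C7 (1 of 2) and 0.90 ± 0.20 for cfh. Of interferon genes 1 of 29 were called higher, 8 adjusted over the list alone (adjusted p = 0.000261), led by irf8 at 1.64 ± 0.39. These 4 lists had adjusted p from 0.229 to 0.536 with an estimated correlation. Higher too were immediate early genes, keratinocytes, cytosolic ribosome, T cells, lysosome, granulocytes, hepatocyte genes, antioxidant genes, pancreatic enzymes, muscle, B cells and autophagy (adjusted p from 1.96e-06 to 0.0372, and adjusted p from 0.229 to 0.704 with an estimated correlation), the hepatocyte list through fah (1.18 ± 0.17) and apoeb (0.93 ± 0.16), which degrade tyrosine and carry lipid. Lower were cholesterol synthesis and neurons (adjusted p from 0.000187 to 0.0128, and adjusted p from 0.229 to 0.646 with an estimated correlation). Without MC10 3345 genes were called, without MC1 164, without MC4 192, without MC5 105, without MC6 210 and without MC9 142. DESeq2 called 1319, and a fit of these 10 brains alone called 7. Of 26 named genes, 1 kept its call in every alternative. Pituitary hormone genes averaged 0.207 ± 2.441 (SD) log2 CPM in 9-week brains, where MC1, MC2 and MC3 lay at -1.298, -1.409 and -1.989, and 2.705 ± 1.876 at 27 weeks, where MC6 lay at -0.256. Pituitary content thus varies between brains, and its part in the calls was not tested.

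In vehicle livers sterol synthesis and chaperones were lower at 27 than at 9 weeks, and muscle genes higher in part of the fish. Of 16750 genes 2072 were called, 785 higher and 1287 lower. First among the falls were -5.76 ± 1.16 for trdn Nfu_g_1_018768, -3.78 ± 0.56 for hivep3a, -3.73 ± 0.71 for APOB (1 of 3) Nfu_g_1_018881, -3.64 ± 0.84 for pcyt1bb and -3.51 ± 0.80 for SI Nfu_g_1_000389. First among the rises were the sarcomere genes 8.55 ± 1.96 for tcap, 8.06 ± 1.75 for smyhc2, 7.74 ± 2.12 for actn2, 7.52 ± 1.97 for MYOM1 (1 of 2) and 7.08 ± 1.84 for desma Nfu_g_1_017784, and adjusted p ran from 0.00582 to 0.0302. The muscle transcripts sit in MC7 and MC8. Without these fish the 5 sarcomere genes read 2.01, 1.11, 0.74, 0.030 and 0.54, 53 genes were called, and none of the genes just named. Of cholesterol enzymes 6 of 23 were called lower, 12 adjusted over the list alone (adjusted p = 2.91e-07), with -2.99 ± 0.51 for MVD, -2.32 ± 0.64 for mvk, -2.57 ± 0.71 for fdps and -1.76 ± 0.46 for nsdhl, which follow each other in the mevalonate and sterol pathway. Of chaperones 11 of 34 were called lower and 1 higher, 12 and 2 adjusted over the list alone (adjusted p = 0.0392), with -1.56 ± 0.35 for hspa4a and -0.91 ± 0.20 for hspa4b. Of hepatocyte genes 6 of 41 were called lower and 1 higher, 6 and 1 adjusted over the list alone (adjusted p = 0.00388), with -1.32 ± 0.30 for apoeb and -1.19 ± 0.32 for apobl. Of muscle genes 6 of 32 were called higher, 9 adjusted over the list alone (adjusted p = 0.000918). These 4 lists had adjusted p = 0.883 with an estimated correlation. Lower too were proteasome and fatty acid oxidation (adjusted p = 0.0337, and adjusted p = 0.883 with an estimated correlation), with psmd11b at -1.70 ± 0.34. Higher were cell cycle, macrophages and mitochondrially encoded subunits (adjusted p from 0.00208 to 0.0341, and adjusted p = 0.883 with an estimated correlation), with mcm7 at 1.29 ± 0.29. The count was 3894 without MC1, 1073 without MC2, 737 without MC3, 873 without MC4, 1083 without MC5, 1380 without MC6, 1186 without MC7 and 778 without MC8, and DESeq2 called 3151. Chaperones (adjusted p = 0.0983) and fatty acid oxidation (0.072) did not pass with the MC10-low trend removed.

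Vehicle skin had fewer collagen transcripts at 27 than at 9 weeks and more immune and pancreatic ones. Of 19285 genes 2019 were called, 716 higher and 1303 lower. The chains of the main fibrillar collagen fell, -2.99 ± 0.76 for col1a1a, -2.88 ± 0.74 for col1a1b and -2.81 ± 0.70 for col1a2, as did -3.17 ± 0.50 for col16a1 and -2.97 ± 0.73 for gatm. Rises were led by 5.16 ± 1.22 for apnl Nfu_g_1_012235, 4.69 ± 1.02 for tceb3 Nfu_g_1_021005, 3.50 ± 0.72 for ankrd1a, 3.35 ± 0.89 for fbxo32 and 3.34 ± 0.71 for crybb1, where fbxo32 marks muscle proteins for degradation, and adjusted p ran from 0.00643 to 0.0307. Of collagens and matrix genes 45 of 82 were called lower, 53 and 1 adjusted over the list alone (adjusted p = 4.9e-21). Of bone and fin ray genes 5 of 24 were called lower, 9 and 1 adjusted over the list alone (adjusted p = 0.0167), with the bone-cell factor sp7 at -2.12 ± 0.51. Of pancreatic enzymes 9 of 11 were called higher, 9 adjusted over the list alone (adjusted p = 8.47e-08), with 2.35 ± 0.45 for cel.1 and 2.92 ± 0.56 for CELA1 (1 of 7). These transcripts are foreign to skin, and their carry-over was not tested. Of interferon genes 8 of 32 were called higher, 9 adjusted over the list alone (adjusted p = 0.000208), with irf8 at 1.36 ± 0.26. Of T-cell genes 4 of 13 were called higher, 6 adjusted over the list alone (adjusted p = 0.000208), with 1.22 ± 0.33 for zap70 and 1.96 ± 0.57 for gzma. Of immediate early genes 6 of 31 were called higher, 10 adjusted over the list alone (adjusted p = 0.000208), with 2.29 ± 0.35 for atf3 and 1.51 ± 0.38 for dusp1. These 6 lists had adjusted p from 0.485 to 0.515 with an estimated correlation. Higher too were complement, macrophages, proteasome, hepatocyte genes, autophagy, lysosome, fatty acid synthesis, B cells and p53 targets (adjusted p from 9.98e-06 to 0.0334, and adjusted p from 0.485 to 0.704 with an estimated correlation), with CD68 at 0.80 ± 0.23 and gadd45g at 2.25 ± 0.56. Lower were complexes II to V, fatty acid oxidation, mitochondrial ribosome, erythrocytes, chaperones and pigment cells (adjusted p from 0.000283 to 0.0334, and adjusted p from 0.485 to 0.743 with an estimated correlation), with ppargc1a at -1.75 ± 0.43. The count was 1156 without MC2, 731 without MC3, 1158 without MC4, 816 without MC5, 1172 without MC6, 1273 without MC8, 878 without MC9 and 3577 without the germ-cell-bearing skins of MC7 and MR30, and DESeq2 called 3239.

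In the brain, the genes that fell most under rotenone include synaptic and calcium-release genes, while the neuron list as a whole did not pass (adjusted p = 0.602, 6 of 57 called lower and 1 higher). No complex I gene was called. Of 20132 genes 1750 were called, 657 higher and 1093 lower. Falls were led by -6.56 ± 1.07 for DMXL2 (1 of 2) Nfu_g_1_009336, -6.28 ± 0.99 for LINGO3 (1 of 2), -5.97 ± 1.03 for ryr3 Nfu_g_1_015312, -5.93 ± 0.90 for MGAT3 (1 of 2), -5.76 ± 0.86 for sept5b and -5.71 ± 0.90 for grin2bb Nfu_g_1_019702, which act at synapses, in calcium release and in glycan assembly. Leading the rises were 4.49 ± 0.97 for asb2a Nfu_g_1_018918, 1.73 ± 0.22 for LONRF2 Nfu_g_1_014894, 1.71 ± 0.23 for SHC1 Nfu_g_1_003210, 1.37 ± 0.17 for arntl1a Nfu_g_1_008319 and 1.35 ± 0.22 for lonrf1l, of which arntl1a is a core clock activator. Adjusted p ran from 0.00181 to 0.0126. These decreased genes read low in the MC10 brain too, labelled vehicle, where DMXL2 (1 of 2) had 0.0 CPM, LINGO3 (1 of 2) 0.0934, ryr3 0.2803, MGAT3 (1 of 2) 0.2336, sept5b 0.327 and grin2bb 0.5606. Of immediate early genes 3 of 33 were called lower, 3 adjusted over the list alone (adjusted p = 0.000319), with fosl1a at -1.18 ± 0.29. Of chaperones 1 of 34 were called higher, 1 adjusted over the list alone (adjusted p = 0.000892), with hspa4a at 0.52 ± 0.11. The muscle list moved through its ryanodine receptors, calcium channels that neurons use too, led by ryr1b Nfu_g_1_002148 at -4.81 ± 0.94, and 5 of 35 were called lower, 5 adjusted over the list alone (adjusted p = 0.00167). Of interferon genes 2 of 29 were called lower, 1 adjusted over the list alone (adjusted p = 0.00876), with PSMB10 at -1.64 ± 0.26. Of macrophage genes 1 of 29 were called lower, 0 adjusted over the list alone (adjusted p = 0.0283), with c1qc at -0.88 ± 0.23. All 5 lists had adjusted p = 0.967 with an estimated correlation. The complex I genes with the smallest p were 0.42 ± 0.15 for ndufs1 Nfu_g_1_017667, -0.25 ± 0.21 for ndufs4, -0.20 ± 0.20 for ndufa6 and -0.23 ± 0.22 for ndufb4, at adjusted p from 0.0902 to 0.595, and without MC10 the last 3 turned to 0.079, 0.11 and 0.14. Without MC10 6584 genes were called, without MC6 881, without MC7 1013, without MC8 1043, without MC9 1018, without MR27 737, without MR29 804 and without MR30 865, and DESeq2 called 2841.

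In the liver, genes of mitochondrial translation, proteasome and sterol synthesis were higher in rotenone than in vehicle fish, and autophagy and clock genes lower. Of 16750 genes 4348 were called, 2336 higher and 2012 lower. First among the rises were 6.58 ± 1.17 for MUC19, 5.66 ± 1.23 for slc12a1 Nfu_g_1_003285, 5.50 ± 1.30 for tcnl, 5.36 ± 1.06 for apoea and 5.15 ± 1.72 for gck, among them a mucin, a salt transporter, an apolipoprotein and glucokinase. Leading the falls were -9.46 ± 1.95 for MFAP4 (9 of 13) and -5.13 ± 1.17 for adcy2a Nfu_g_1_001711, with -6.18 ± 1.55 for smyhc2, -4.93 ± 1.70 for MYOM1 (1 of 2), -4.65 ± 1.39 for gmpr and -4.56 ± 1.49 for tcap, with adjusted p from 0.0022 to 0.0448. The last 4 follow the muscle transcripts of vehicle fish MC7 and MC8, and without these they read 0.74, 2.54, 0.98 and 1.95. Of mitochondrial ribosomal proteins 44 of 62 were called higher, 48 adjusted over the list alone (adjusted p = 1.36e-16), with 1.33 ± 0.17 for MRPL51 and 1.4 ± 0.23 for mrpl46. Of proteasome subunits 31 of 44 were called higher, 31 adjusted over the list alone (adjusted p = 2.66e-10), with 1.89 ± 0.34 for psmd11b and 1.59 ± 0.28 for psmd13. Of cholesterol enzymes 17 of 23 were called higher and 1 lower, 20 and 1 adjusted over the list alone (adjusted p = 8.26e-09), with 3.17 ± 0.51 for MVD, 2.16 ± 0.35 for PMVK and 2.60 ± 0.47 for nsdhl. Of chaperones 16 of 34 were called higher, 18 and 2 adjusted over the list alone (adjusted p = 2.89e-06), with 2.56 ± 0.46 for hyou1 and 1.39 ± 0.24 for hspa9. Of autophagy genes 11 of 33 were called lower and 2 higher, 12 and 2 adjusted over the list alone (adjusted p = 0.00937), with map1lc3b at -2.0 ± 0.30. Of clock genes 9 of 28 were called lower and 4 higher, 11 and 4 adjusted over the list alone (adjusted p = 0.049), with -3.63 ± 0.58 for nr1d1, -1.93 ± 0.28 for tefb and -1.76 ± 0.21 for dbpb. Of nuclear complex I subunits 4 of 30 were called higher, 1 adjusted over the list alone (adjusted p = 0.00537), namely 0.75 ± 0.19 for ndufv2, 0.55 ± 0.16 for ndufs8b, 0.71 ± 0.22 for ndufb6 and 0.62 ± 0.21 for ndufa13. These 7 lists had adjusted p from 0.65 to 0.833 with an estimated correlation. Lower too were lysosome, B cells, collagens and matrix, macrophages and muscle (adjusted p from 0.000985 to 0.0283, and adjusted p = 0.793 with an estimated correlation), with ebf1b at -2.89 ± 0.73. Higher were cytosolic ribosome, complexes II to V, fatty acid oxidation and pancreatic enzymes (adjusted p from 0.000137 to 0.0149, and adjusted p from 0.793 to 0.833 with an estimated correlation), with ECI2 at 1.12 ± 0.20. Without MC7 and MC8 1884 genes were called, and the complex I subunits (0.76, 0.47, 0.70 and 0.60) and gck (4.84) were not. The count was 2740 without MR27, and gck lost its call without MC10 (4.96). Removing the MC10-low trend gave 3800 calls, with 2978 of the 4348 kept, and ended the results for complex I (adjusted p = 0.603), complexes II to V (0.603), cytosolic ribosome (0.841), fatty acid oxidation (0.244) and clock (0.603). As the MC10 brain reads near rotenone brains, this offset, here and in skin, may remove drug effects and cannot mark lost lists as artefacts.

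In skin, mitochondrial translation, chaperone and sterol genes were higher in rotenone than in vehicle fish, and autophagy, pancreatic and clock genes lower. Of 19285 genes 2365 were called, 1365 higher and 1000 lower. Rises were led by 2.58 ± 0.35 for TIMM44 (1 of 2) Nfu_g_1_020420, 2.33 ± 0.30 for atad3b, 2.09 ± 0.27 for XPO5, 1.95 ± 0.32 for DHX30 and 1.83 ± 0.34 for prmt5, of which TIMM44, atad3b and DHX30 act in mitochondrial import, nucleoids and ribosome assembly. First among the falls were -4.08 ± 0.93 for fbxo32, -3.85 ± 1.14 for apnl Nfu_g_1_012235, -2.92 ± 0.51 for lpin1 Nfu_g_1_018267, -2.85 ± 0.76 for zbtb20 Nfu_g_1_005402 and -2.82 ± 0.58 for syne2a, with adjusted p from 0.00205 to 0.0409. Of mitochondrial ribosomal proteins 29 of 62 were called higher, 41 adjusted over the list alone (adjusted p = 3.93e-15), with 0.86 ± 0.16 for MRPL51 and 0.77 ± 0.14 for mrps31. Of chaperones 16 of 34 were called higher, 19 adjusted over the list alone (adjusted p = 3.54e-11), with 1.5 ± 0.20 for hyou1 and 1.41 ± 0.19 for hsp90b1. Of cholesterol enzymes 5 of 22 were called higher, 11 adjusted over the list alone (adjusted p = 1.95e-05), with 1.41 ± 0.39 for mvk and 1.19 ± 0.24 for ebp. Of autophagy genes 9 of 35 were called lower and 1 higher, 11 and 1 adjusted over the list alone (adjusted p = 0.000147), with -1.66 ± 0.25 for foxo1a and -0.89 ± 0.20 for map1lc3b. Of pancreatic enzymes 7 of 11 were called lower, 9 adjusted over the list alone (adjusted p = 2.71e-06), with -1.94 ± 0.44 for cel.1 and -2.0 ± 0.49 for amy2a, transcripts foreign to skin whose carry-over was not tested. Of clock genes 9 of 28 were called lower and 4 higher, 11 and 5 adjusted over the list alone (adjusted p = 0.00705), with -2.32 ± 0.32 for nr1d1 and -1.77 ± 0.24 for dbpb. Of nuclear complex I subunits 3 of 30 were called higher, 0 adjusted over the list alone (adjusted p = 2.16e-05), namely 0.48 ± 0.14 for ndufb9, 0.55 ± 0.16 for ndufb6 and 0.44 ± 0.14 for ndufv2, while ndufv3 read 0.38 ± 0.12 (adjusted p = 0.0542). These 7 lists had adjusted p from 0.411 to 0.64 with an estimated correlation. Lower too were B cells, keratinocytes, T cells, macrophages, lysosome, complement and immediate early genes (adjusted p from 0.000435 to 0.0427, and adjusted p from 0.411 to 0.807 with an estimated correlation), with zap70 at -1.11 ± 0.32. Higher were complexes II to V, fatty acid oxidation, proteasome, glycolysis and cell cycle (adjusted p from 9.54e-07 to 0.042, and adjusted p from 0.64 to 0.919 with an estimated correlation), with acads at 0.84 ± 0.18. The count was 1402 without MC6, 1271 without MC9, 1384 without MR29 and 3764 without MC7 and MR30, and without MC10 ndufb6 (0.56) and ndufv2 (0.42) lost their calls. With the MC10-low trend removed 1736 genes were called, with 1462 of the 2365 kept, and complex I (adjusted p = 0.421), complexes II to V (0.0919), fatty acid oxidation (0.0919), proteasome (0.624), clock (0.126), glycolysis (0.116) and cell cycle (0.538) did not pass. The heat map sets the lists of all comparisons side by side.

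**Figure D3:**
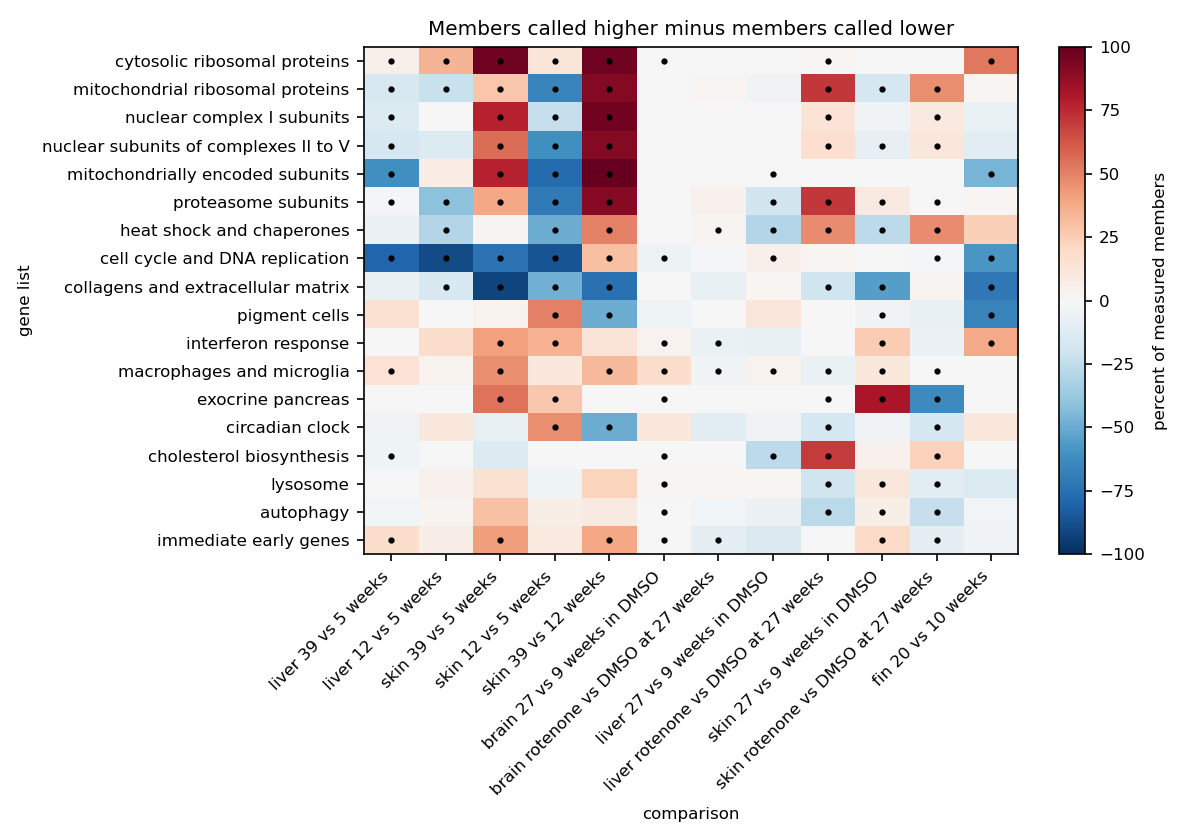
Percent of measured list members called higher minus percent called lower, for 18 lists and 12 comparisons. Dots mark lists past the set test.

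Most genes called both under rotenone and with age had opposite directions. In the liver, where aging and treated fish are different animals, this held for 317 of 416 genes called in both (76.2 percent, 39 against 5 weeks), and in skin for 598 of 991 (60.34 percent). By sign alone, called under rotenone or not, it held for 61.81 percent of age-called genes in liver and 54.98 in skin. Mitochondrial ribosomal proteins fell in the liver from 5 to 39 weeks and rose under the drug (adjusted p = 6.63e-08 and 1.36e-16, and 0.705 and 0.65 with an estimated correlation). Skin has no single direction for them with age, as they were lower at 12 than at 5 weeks and higher at 39 weeks. Over all genes r was -0.217 in the liver (rho -0.243) and -0.102 in skin (rho -0.123), and genes are not independent replicates. Without MC7 and MC8 the liver gave -0.128, and without MC7 and MR30 skin gave -0.166. Against the step from 5 to 27 weeks r was -0.382 and -0.395. In the treated arm r was -0.376 in brain, -0.562 in liver and -0.248 in skin, but the 27-week vehicle libraries enter both differences. Differences of group means gave -0.237, -0.554 and -0.523, and simulated ones with no relation -0.506, -0.497 and -0.499 from that sharing, so such values say little by themselves. With separate vehicle fish for each difference, the median r was -0.324 in the liver (20 of 20 divisions below 0) and -0.252 in skin (17 of 20). The brain value turned to 0.071 (10 of 20), and without the MC10 brain it was -0.388, below 0 in 6 of 6.

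Clock genes separated vehicle and rotenone fish at 27 weeks in all 3 tissues, with 13 of 28 called in brain, in liver and in skin. Under rotenone the activators arntl1a in brain and clock in liver and skin rose, and the repressor nr1d1 and the output gene dbpb fell in liver and skin. A clock score, whose axis came from untreated fish and is positive where nr1d1 reads high, was 1.62 ± 1.10 in vehicle brains, -1.31 ± 0.35 under rotenone and -0.31 ± 0.40 in 9-week vehicle brains (mean ± SD, 5 fish each). The liver gave 3.19 ± 1.13, -2.32 ± 2.02 and -0.88 ± 1.57, and skin 2.43 ± 0.83, -1.97 ± 0.96 and -0.46 ± 1.36. Clock genes called between vehicle fish of 27 and 9 weeks numbered 7 in brain, 7 in liver and 9 in skin, and between rotenone and 9-week vehicle fish 5, 5 and 1. Within groups, the scores of the same 15 fish correlated between liver and skin at r = 0.739 (rho 0.718, permutation p = 0.00407, adjusted p = 0.0122 over 3 tissue pairs, r = 0.527 without the 2 farthest fish). Brain and skin gave r = 0.513 (rho 0.521, permutation p = 0.0191, adjusted p = 0.0286, but 0.0743 for rho, r = 0.465 without the 2 farthest), and brain and liver r = 0.366 (rho 0.357, permutation p = 0.101, r = 0.356 without the 2 farthest). The plot of clock scores shows every library.

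**Figure D4:**
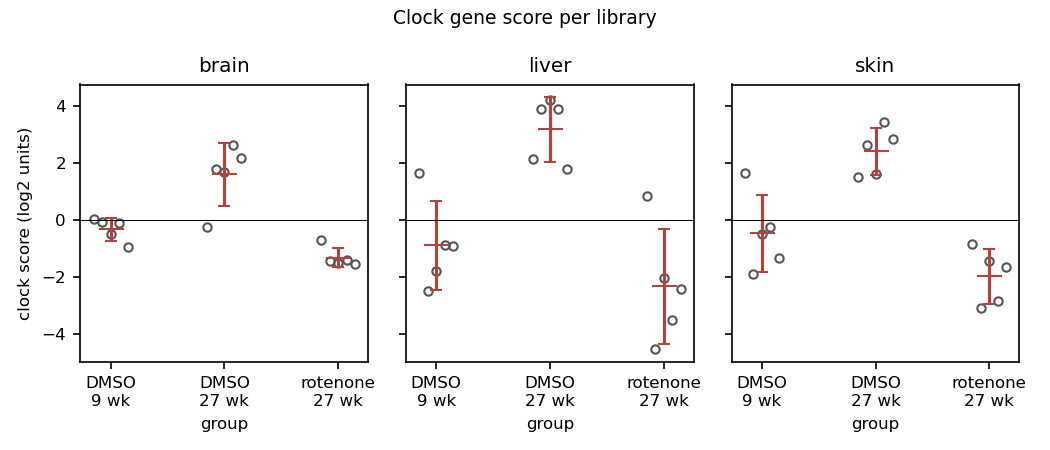
Clock score of each library in brain, liver and skin for 9-week vehicle, 27-week vehicle and 27-week rotenone fish. Bars give mean ± SD of 5 fish.

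Aging changes were partly shared between tissues. Cell cycle genes fell in liver and skin from 5 to 12 weeks and in fins from 10 to 20 weeks (adjusted p = 0.137, 0.483 and 0.29 with an estimated correlation), and collagens in skin and fins (adjusted p = 0.483 and 0.0247 with an estimated correlation). Liver and skin changes from 5 to 39 weeks correlated at r = 0.425 (rho 0.413), with 488 genes higher in both where 232.6 are expected by chance and 771 lower in both against 330.1. Some fish gave both tissues, and genes are not independent replicates. Fin and skin gave r = 0.321 (rho 0.284), with 989 and 1134 shared calls against 551.1 and 671.6. Untreated and vehicle aging gave r = 0.317 (rho 0.284) in liver, with 117 and 84 shared calls against 41.6 and 88.4, and 0.314 (rho 0.309) in skin, with 396 and 589 against 181.6 and 373.7.

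In fins of the same 45 fish, matrix, pigment and proliferation genes fell from 10 to 20 weeks, and ribosomal and interferon genes rose. Of 18828 genes 4581 were called, 2161 higher and 2420 lower, with both clips of a fish compared within that fish. Without pairing by fish 3877 were called. Falls were led by -2.89 ± 0.59 for pvalb3, -1.91 ± 0.35 for apnl Nfu_g_1_012235, -1.65 ± 0.26 for scpp7, -1.60 ± 0.25 for col10a1 Nfu_g_1_022498 and -1.59 ± 0.23 for cd248b Nfu_g_1_005373, among them a calcium buffer, a mineral-matrix protein and a cartilage collagen. Leading the rises were 1.45 ± 0.13 for GFRA4 (2 of 2), 1.17 ± 0.14 for stxbp5l, 1.16 ± 0.060 for tbx3 Nfu_g_1_006786, 1.15 ± 0.16 for CCL25 (2 of 2) and 1.08 ± 0.11 for hsp70.1, among them a growth-factor receptor, a limb transcription factor and a chemokine. Adjusted p ran from 1.83e-20 to 0.000206. Of collagens and matrix genes 58 of 78 were called lower and 2 higher, 63 and 3 adjusted over the list alone (set test adjusted p = 8.94e-33, adjusted p = 0.0247 with an estimated correlation), with -0.82 ± 0.082 for col6a1 and -1.02 ± 0.10 for col11a1b. Of pigment-cell genes 18 of 27 were called lower, 21 and 1 adjusted over the list alone (set test adjusted p = 9.67e-15, adjusted p = 0.0247 with an estimated correlation), with the melanosome genes -1.16 ± 0.11 for oca2 and -0.72 ± 0.055 for gpr143. No other list of any comparison passed with an estimated correlation. Of cell cycle and replication genes 34 of 57 were called lower and 1 higher, 36 and 1 adjusted over the list alone (adjusted p = 3.97e-17), with -1.08 ± 0.17 for tpx2 and -0.72 ± 0.079 for smc4. Of bone and fin ray genes 8 of 24 were called lower and 1 higher, 10 and 3 adjusted over the list alone (adjusted p = 0.0106), with the fin-ray fibre genes -1.54 ± 0.15 for and2 and -1.12 ± 0.12 for and1. Of cytosolic ribosomal proteins 40 of 74 were called higher and 1 lower, 53 and 1 adjusted over the list alone (adjusted p = 1.67e-10), with rplp2 at 0.26 ± 0.055. Of interferon genes 12 of 32 were called higher, 12 adjusted over the list alone (adjusted p = 9.25e-05), with stat1b at 0.27 ± 0.066. These 4 lists had adjusted p from 0.268 to 0.576 with an estimated correlation. Lower too were mitochondrially encoded subunits, fatty acid oxidation and astroglia (adjusted p from 0.00496 to 0.00721, and adjusted p from 0.29 to 0.547 with an estimated correlation), with acaa2 at -0.41 ± 0.058. Higher were T cells and complement (adjusted p from 0.0106 to 0.0108, and adjusted p from 0.482 to 0.501 with an estimated correlation), with zap70 at 0.45 ± 0.12 and C4A at 0.77 ± 0.14. Short-lived, middle and long-lived fish alone gave 750, 1118 and 313 calls, and 176 genes changed at least 2-fold.

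Long-lived fish did not differ in any single fin gene from fish that died early. Death came at 28.7 to 36.4 weeks in the short-lived and at 57.3 to 71.9 weeks in the long-lived group, 15 fish each. edgeR and DESeq2 both called 0 genes at 10 weeks (18273 tested, 630 with an unadjusted p under 0.05), at 20 weeks (18331 and 674) and for the change between clips (18828 and 320). The smallest p at 10 weeks belonged to 0.55 ± 0.14 for hoxd11a, -1.35 ± 0.37 for CRTAM and 0.22 ± 0.064 for fam160a2 (adjusted p = 0.889), at 20 weeks to -1.5 ± 0.36 for aldoaa, -0.92 ± 0.23 for erbb4a Nfu_g_1_003743 and 0.83 ± 0.23 for tjap1 Nfu_g_1_007805 (adjusted p = 1.0), and for the change to 0.49 ± 0.12 for nxn, 1.61 ± 0.42 for STAC Nfu_g_1_022802 and -0.35 ± 0.11 for zmynd8 Nfu_g_1_021458 (adjusted p = 0.995). Several lists passed the set test with 0 members called, also adjusted over the list alone. Long-lived fish at 10 weeks were lower in mitochondrial ribosomal proteins (median -0.16), proteasome subunits (median -0.19) and complex I (median -0.089), and these lists had adjusted p from 6.61e-12 to 1.32e-05, and adjusted p from 0.53 to 0.636 with an estimated correlation. Lower with them were complexes II to V, chaperones, macrophages, cytosolic ribosome, cholesterol synthesis, unfolded protein response, immediate early genes, glycolysis and fatty acid oxidation (adjusted p from 1.17e-09 to 0.0275, and adjusted p from 0.53 to 0.863 with an estimated correlation), and higher were pigment cells, collagens and matrix and autophagy (adjusted p from 0.000824 to 0.0412, and adjusted p from 0.443 to 0.735 with an estimated correlation). At 20 weeks complex I had a median of -0.034 (set test adjusted p = 0.00341, adjusted p = 0.974 with an estimated correlation), lower were cytosolic ribosome and complexes II to V (adjusted p from 1.82e-12 to 0.00718, and adjusted p = 0.974 with an estimated correlation), and higher were collagens and matrix, pigment cells and mitochondrially encoded subunits (adjusted p from 5.53e-16 to 0.00341, and adjusted p from 0.822 to 0.974 with an estimated correlation). Of the MC10-low genes 0 of 592 were called at either age, but their median was 0.28 at 10 weeks (r with the MC10 difference -0.373) and 0.26 at 20 weeks (r = -0.323), and that trend was not removed from the fins. The change between clips was more positive in long-lived fish for proteasome, mitochondrial ribosome, macrophages, collagens and matrix, chaperones, complexes II to V, glycolysis, unfolded protein response, cholesterol synthesis, mitochondrially encoded subunits and B cells (adjusted p from 5.99e-06 to 0.0308, and adjusted p from 0.799 to 0.839 with an estimated correlation). Complex I genes with the smallest p were -0.18 ± 0.093 for ndufa13 and -0.19 ± 0.10 for ndufa11 at 10 weeks, -0.45 ± 0.20 for ndufs1 Nfu_g_1_017667 and -0.11 ± 0.055 for ndufb5 at 20 weeks and -0.52 ± 0.35 for ndufs1 Nfu_g_1_017667 and 0.16 ± 0.13 for ndufs8b for the change.

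The mean of nuclear complex I subunits was 4.774 ± 0.1287 (SD) log2 CPM in long-lived and 4.8534 ± 0.2238 in short-lived fish at 10 weeks, a difference of -0.080 (permutation p = 0.252, adjusted p = 0.272). At 20 weeks it was 4.7554 ± 0.1458 and 4.8091 ± 0.1194, a difference of -0.054 (permutation p = 0.272, adjusted p = 0.272). The first batch, 10 fish per group, gave -0.062 and -0.026 (permutation p = 0.513 and 0.614), and the second, 5 per group, -0.114 and -0.110 (permutation p = 0.318 and 0.323). Within lifespan groups, age at death and the complex I mean had r between -0.205 and 0.285 over 6 tests (adjusted p = 0.996, rho adjusted p = 0.874). From short-lived to long-lived, r was 0.001, 0.285 and -0.205 at 10 weeks and 0.054, 0.033 and 0.032 at 20 weeks, and -0.331, 0.105, -0.435, 0.368, 0.039 and 0.155 without the 2 farthest fish. In the first batch alone the 6 values were 0.125, 0.314, -0.062, -0.575, 0.353 and 0.126, and -0.364, -0.188, -0.815, -0.261, -0.12 and -0.368 without the 2 farthest fish. The scatter against age at death shows every fish.

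**Figure D5:**
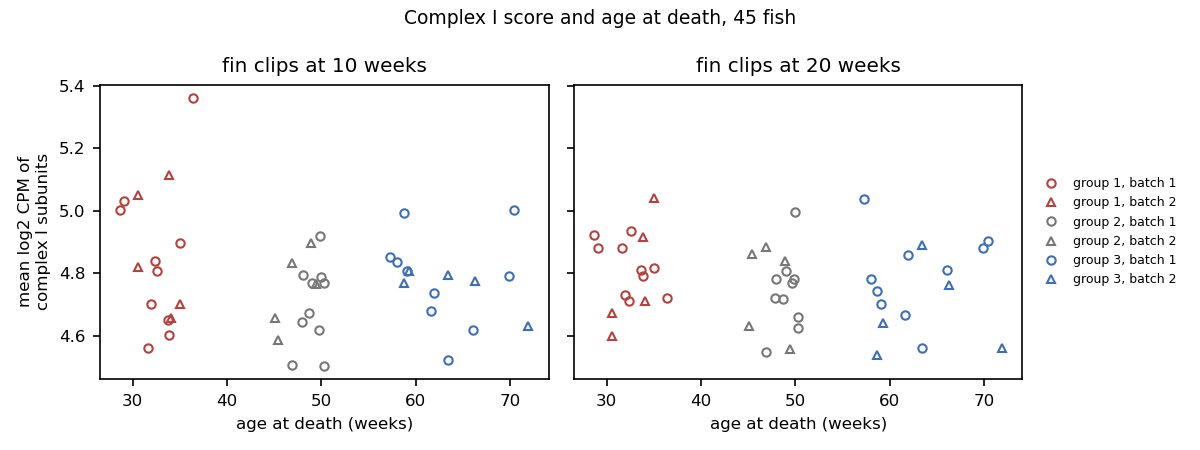
Mean log2 CPM of nuclear complex I subunits in fins against age at death, at 10 and 20 weeks. Circles are the first batch and triangles the second.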

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

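The tests of the patterns below, and the shuffles for the liver ages, brain rotenone, fin ages and fin lifespan at 10 weeks, were chosen only after the result was seen, whereas the shuffles for the remaining comparisons were chosen before. Each comparison was repeated with its group labels shuffled, in 100 groupings that include the real one.

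For livers the 2277 calls across all ages were reached by 1 grouping, the real one, with 2002 as the highest other. The 2111 calls between 39 and 5 weeks were matched by 1 other grouping (2 of 100, highest other 2142), and the 2383 between 12 and 5 weeks by none (1 of 100, highest other 2). For skin, 1 of 100 reached the real count across all ages (12580, highest other 2462), between 39 and 5 weeks (10316 and 4434), 12 and 5 weeks (5913 and 578) and 39 and 12 weeks (9340 and 5222). The same held for liver rotenone (4348 and 1389), skin rotenone (2365 and 1789), skin from 9 to 27 weeks (2019 and 773) and fin ages, tested by limma on the change of each fish (4601 and 33). The vehicle liver from 9 to 27 weeks had 2 of 100 (2072, highest other 3136). At most 2 of 100 groupings thus reached each real count named so far, and 100 groupings per comparison cannot exclude chance. Another grouping called more than the real one in this liver comparison and in the liver between 39 and 5 weeks. Without MC7 and MC8 the vehicle liver gave 53 calls, and no shuffle was made without them. In the brain 4 of 100 were as large from 9 to 27 weeks (420, highest other 1178) and under rotenone (1750, highest other 4632). Other groupings of the same brains thus call several times the real number, which points to a structure of these samples beside the groups. For the liver between 39 and 12 weeks (0, highest other 645) and the fin lifespan contrasts at 10 weeks (0 and 351), at 20 weeks (0 and 17) and for the change (0 and 1008), the real count is 0, so all 100 groupings are as large by construction, and the shuffles say nothing on chance. Groupings with 645 or 1008 calls where the real one has 0 point to a structure of these samples, which was not tested.

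Libraries far from the other 4 of their group were looked for in 154 groups and measures. Chance flags about 1 in 20 groups, so about 8 were expected, and 19 were found. Depth set apart the 20-week liver of JM84 (31.38 M counts, others 21.74 to 24.48), the 9-week vehicle skin of MC3 (45.95, others 27.14 to 29.62) and the vehicle liver of MC9 (26.51, others 30.78 to 32.49). The share of the 20 most abundant genes was 26.93 percent in the 20-week skin of JM79 (others 29.53 to 29.69) and 15.85 percent in the brain of MC10 (others 10.04 to 10.63). Mitochondrial ribosomal and transfer RNA made up 0.2914 percent in the 39-week skin of JM18 (others at most 0.2177), 0.6049 in the rotenone brain of MR27 (others at least 0.7164) and 0.4727 in the rotenone skin of MR26 (others at most 0.1534).

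Marker lists set apart the 5-week liver of JM103 (yolk 5.761, others at most -0.346), the 12-week skin of JM109 (hepatocyte 6.313, others at most 2.772), and the skins of MC7 (testis 5.549, others at most -0.299) and MR30 (testis 6.672, others at most -1.263). Muscle genes did so in the 39-week liver of JM15 (2.666, others at most 0.388), the vehicle skin of MC9 (5.144, others at least 5.516) and the rotenone brain of MR29 (0.72, others at least 1.161). The clock score of the rotenone brain of MR26 was -0.701 (others at most -1.38). The MC10 brain stood apart in mitochondrial protein transcripts (11.567 percent, others at most 7.334), in long genes (median -0.454, others at least 0.067) and in the genes lower in 39-week skins (score -2.021, others at least 0.631).

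Clock genes moved together in all 3 tissues of the treated arm. Fish of the 3 groups sampled at different times of day may account for this, because the axis along which clock genes vary among untreated fish of 1 age runs against the rotenone changes, with r across clock genes of -0.585 in brain and stronger values in liver and skin. Rotenone acting on the clock stays open for the difference between rotenone and vehicle fish. At least 25 percent of clock genes were called between vehicle fish of 27 and 9 weeks in each tissue, but these fish had no rotenone, so by design that count tests nothing about the drug. Age stays open for the vehicle fish and was not tested, and sampling times are not used here.

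Changes under rotenone ran against those with age. The 27-week vehicle libraries enter both differences. In the brain dividing them gave a median r of 0.071, so sharing cannot be told from an effect of the drug there. Without the MC10 brain it was -0.388 (-0.505 to -0.302, 6 of 6 divisions). In skin (-0.252, 17 of 20 below 0, -0.429 without MC7 and MR30) sharing is not the whole source. In the liver (-0.324, 20 of 20) no division left out MC7 and MC8, so sharing stays open there. Removing the MC10-low trend moved r with untreated aging from -0.217 to -0.249 in liver and -0.102 to -0.31 in skin. That trend is thus not the source. An effect of rotenone opposite to that of age stays open, and a clock or sampling-time difference was not separated from it.

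Genes low in the MC10 brain were low in all 39-week skins (highest score -0.85, where no 12-week skin lay below 0.61), with a median difference from 12-week skins of -2.647. A yield that depends on the transcript, differing between libraries, is a candidate explanation, since 1 gene set moves in a brain, in skins and, with a median of -1.13, in rotenone livers. Gene length is not the whole source, as the median was -2.599 with a trend on length removed. A wrong label on the MC10 brain stays open. On genes called under rotenone without it, it read 1.48 and rotenone brains 0.86 to 1.18. Other vehicle brains of its age read at most 0.09, younger ones 0.14 to 0.58. MC10 read 1.06 on genes called higher (rotenone 0.76 to 1.06) and 0.92 on those with an MC10 difference above -1 (0.8 to 1.07). Yet its own fish's liver and skin matched it best at 2 of 3 gene numbers. Age itself stays open for the skins and was not tested, as no label gives a library batch for the 39-week skins, and GC content was not analysed here.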

How the results depend on the processing

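Fits with a length or MC10-low trend removed and those without pairs or single libraries taken to stand apart were chosen after seeing the data, and the remaining alternatives before. Of 720 named genes 428 kept direction and side of the threshold in every alternative but the removed trends, 283 lost their call in at least 1 of these, 5 gained one and 11 turned. With the MC10-low trend removed 2 more turned. No alternative moved the counts for skin across ages, skin between 39 and 5 weeks or the 3 fin lifespan contrasts by more than 1.5 times, and the age effects compared between tissues kept their direction.

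DESeq2 gave 4816 calls for any age difference in the liver, 508 for 39 against 12 weeks, 1319 for vehicle brain ages, 2841 for brain rotenone, 3151 for vehicle liver ages and 3239 for vehicle skin ages. A slope on age called 1400 liver genes. Fits of the compared groups alone called 3673 for liver 12 against 5 weeks, 7 for vehicle brain ages, 802 for brain rotenone, 1279 for vehicle liver ages and 1348 for skin rotenone, where fewer samples estimate the spread. Asking for a 2-fold change left 3429 for skin 12 against 5 weeks, 6067 for 39 against 12 weeks, 145 and 638 for the brain (age, rotenone), 1200 and 2367 for the liver, 960 and 733 for skin and 176 for fin ages.

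Without JM103 and JM100 732, 1118 and 1036 liver genes were called (any age, 39 against 5, 12 against 5 weeks). Without MC10 3345 and 6584 brain genes were called, without MC7 and MC8 53 and 1884 liver genes, and without MC7 and MR30 3577 and 3764 skin genes, each for age and for rotenone. Removing the length trend gave 792 for vehicle brain ages. Removing the MC10-low trend gave 4259 for skin 39 against 12 weeks, 1276 for vehicle brain ages and 3402 for brain rotenone. Fish of 1 lifespan group alone gave 750, 1118 and 313 fin genes, from fewer samples. Unpaired, the fin ages called 3877. With a correlation estimated per list 2 gene set results passed, against 218.

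Leaving out 1 library gave 1107 to 3718 calls for any liver age difference, 1214 to 2634 for 12 against 5 weeks and 0 to 118 for 39 against 12 weeks. Vehicle age ranged from 105 to 3345 in brain, 737 to 3894 in liver and 731 to 2425 in skin, and rotenone from 737 to 6584, 2740 to 4576 and 1271 to 3177. The ranges of the other counts were 1417 to 2235 (liver 39 against 5 weeks), 9534 to 10663, 4162 to 5783 and 8393 to 9814 (skin 39 against 5, 12 against 5 and 39 against 12 weeks).

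The correlation between rotenone and age took the values -0.382 (27 against 5 weeks), -0.458 (its called genes), -0.562 (vehicle ages), -0.815 (their called genes) and -0.324 (divided vehicle libraries) in liver. In skin these were -0.395, -0.559, -0.248, -0.783 and -0.252, and -0.31 with the MC10-low trend removed. Vehicle ages gave -0.612 in skin without MC7 and MR30, and in brain -0.668 for called genes, -0.536 without MC10 and 0.071 with divided libraries.

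Reversals were few. Without JM103 and JM100 b3gat1 read 2.04 between 12 and 5 weeks. With the MC10-low trend removed eif2ak2 Nfu_g_1_016090 read 0.19 (skin, 39 against 5 weeks) and roraa Nfu_g_1_008006 0.97 (39 against 12). For ndufs4, brain rotenone vs DMSO at 27 weeks, the value was -0.347 without MC8 and 0.079 without MC10. For ndufa6, brain rotenone vs DMSO at 27 weeks, it was -0.287 without MC8 and 0.11 without MC10, and for ndufb4, brain rotenone vs DMSO at 27 weeks, -0.32 without MC9 and 0.14 without MC10. Without MC7 and MC8 liver rotenone values turned for smyhc2 (0.74), MYOM1 (1 of 2) (2.54), gmpr (0.98), tcap (1.95), ldb3b Nfu_g_1_023306 (0.65), ttnb (0.64) and ttna Nfu_g_1_019261 (0.77). The correlation of the score with age at death, between -0.205 and 0.285 in the fits reported, became -0.034 (short-lived, 10 weeks), -0.15 (short-lived, 20 weeks) and -0.013 (middle, 20 weeks) with complexes II to V, and -0.009 with RLE factors (short-lived, 10 weeks). With ribosomal proteins it became -0.305 and 0.25 at 10 weeks and -0.241 and -0.081 at 20 weeks (middle, long-lived), and with the first batch -0.575 (short-lived, 20 weeks). Except where named, the cause was not tested. Of 50 changes of 1.5-fold put into the counts, 0 to 24 percent were recovered in the tissue comparisons tried and 94 percent between fin ages, so small changes go largely unseen with 5 fish per group.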

Other observations

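All tests here were chosen only after the result was seen. Repeat clips of a fish were more alike than clips of different fish on average, not in each fish. The 10-week and 20-week fin profiles of 1 fish had a median r of 0.27 after group means were removed, against -0.006 between fish, and 37 of 45 fish had r above 0.1. The lowest r was -0.201, and for only 19 of 45 fish was the own clip the best match.

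Brain libraries were compared with the liver and skin of the same fish. Among the 14 fish other than MC10, the own fish was the best match in 11, 11 and 10 at 20, 50 and 100 genes, while MC2, MC3 and MC7 matched another fish better at each number. The MC10 brain matched MR26 best at 20 genes (r = 0.635, own fish 0.362) and its own fish at 50 (0.627) and 100 (0.554).

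The set of low genes depends on its threshold, chosen after the data were seen. With at least 4-fold lower in MC10 it held 1430 measured genes in skin (median -2.231 between 39 and 12 weeks, 1230 called lower), and with 16-fold 292 (median -2.864, 266 called lower). Long-gene transcripts, of at least 8000 nucleotides, had a median deviation under rotenone of -0.225 ± 0.043 (SD over 5 fish) in brain, -0.381 ± 0.169 in liver and -0.159 ± 0.103 in skin, where vehicle fish of 27 weeks had 0.001 ± 0.256, -0.008 ± 0.13 and -0.016 ± 0.075. The vehicle brains spread widely because of MC10 (-0.454).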
